A study of Homo sapiens with 18 samples.

How the data were processed

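The deposited values were raw counts per gene, made by the authors in 2 tables, 1 for each line, with 39368 genes each and 18 libraries in all. Per the labels' protocols, total RNA was isolated with the miRNeasy kit, and libraries were made with the RNA HyperPrep kit with RiboErase, which removes ribosomal RNA and keeps transcripts without poly(A) tails. Per the submitters' processing notes, reads were handled with CASAVA 1.8.2 and aligned with STAR 2.7.9a to GRCh38.p7. The counting tool, the gene annotation, the strand setting, the read length and the hairpin sequences are not given in the sources used here. Among counts of 1 to 20, 68.3% to 72.5% were even in each library, so mates of a pair may have been counted separately, and no correction was made for this beyond a trial with halved counts. Every column of the tables had a sample.

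Each line was fitted alone, with its 3 groups of 3 libraries in 1 model of the group. edgeR 4.0.16 was used with filterByExpr, TMM normalization, glmQLFit and glmQLFTest, and genes were called at a Benjamini-Hochberg adjusted p below 0.05. The contrasts were each shRNA against the vector control and shAhR-1 against shAhR-2. A gene called with both shRNAs had to be called in both contrasts with the same sign, and a gene called in all 4 contrasts had to be so in both lines. The interaction came from 1 fit of all 18 libraries and 6 groups, as the mean of both shRNAs minus control in BE2C less the same in Kelly. SE values were taken from the fold change and the F statistic. CPM values use TMM library sizes. For a check of the labels, the log-CPM of each shRNA library less the mean of its controls was correlated with the fold changes of each shRNA in the other line. For AHR, rate ratios pool the counts of a group, with exact 95% intervals. A fitted fold for a gene at 0 in a group depends on the prior count and is no bound, so list medians were also taken with such genes at a bound from a floor of 3 counts over the group.

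The 20 gene lists were fixed before the data were examined and held 420 genes, 1 of them found under an older symbol. They were AhR targets, AhR complex and partners, adrenergic core regulators, mesenchymal state, catecholamine synthesis and storage, neuronal differentiation, retinoic acid pathway, MYC targets, cell cycle, p53 targets, interferon response, integrated stress and unfolded protein response, cholesterol biosynthesis, hypoxia response, TGF-beta response, Schwann cell and glial markers, fibroblast markers, leukocyte markers, mitochondrially encoded mRNAs and replication-dependent histones. Lists were tested with camera in limma 3.58.1 on log-CPM with a prior count of 2, at the preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a contrast. Counts adjusted over the list alone repeat the adjustment on the members only.

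Named genes were picked by a rule fixed in advance. AHR came first, followed by ARNT, CYP1A1, CYP1B1, TIPARP, AHRR, MYCN, HAND2 and GATA3 whether called or not. Some genes that the rule picks or the lists hold are not reported here by name, and they stay in every count. Per line, genes called in the same direction with both shRNAs were kept when all 6 shRNA libraries lay beyond the 3 controls. The mean CPM also had to be at least 5 and the symbol not a clone name (4100 genes in BE2C, 3538 in Kelly). The 6 risers and 6 fallers with the largest smaller fold change were named, with up to 2 of each direction from each list. The same was done for 6 of each direction over all 4 contrasts, 4 of each sign for the interaction and 3 of each sign between the hairpins. Locations are from GENCODE release 29, and genes listed under newer symbols were matched by gene identifier.

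Alternatives were RLE size factors, no filter beyond a total count above 0, a mean CPM of at least 1, a replicate block, leaving out each library in turn, a fit of only the 2 groups compared, and the Wald test of DESeq2 1.42.0. Halved counts and a run without mitochondrial genes were added later. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

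The methods were tested on simulated data. In negative binomial counts drawn from the fitted means and dispersions, 200 genes were changed, 50 for each fold size. At 1.25-fold, 62% were recovered in BE2C with shAhR-1, 60% with shAhR-2, 60% between the hairpins and 58% with both. The same shares were 74%, 72%, 70% and 70% in Kelly, and 54% in all 4 contrasts and for the interaction. At 1.5-fold they were 70%, 68%, 72% and 68% in BE2C, 72%, 76%, 80% and 72% in Kelly, 66% in all 4 contrasts and 72% for the interaction. At 2-fold they were 82%, 84%, 76% and 82% in BE2C, 84%, 88%, 84% and 84% in Kelly, 76% in all 4 contrasts and 88% for the interaction. At 4-fold they were 86%, 88%, 86% and 86% in BE2C, 94%, 92%, 94% and 92% in Kelly, 84% in all 4 contrasts and 90% for the interaction. Falsely called genes numbered 16, 13, 8 and 1 in BE2C, 6, 8, 9 and 0 in Kelly, 0 in all 4 contrasts and 8 for the interaction, of 13647 to 16258 unchanged genes. In the real contrasts within a line 52.3% to 77.4% of genes were called, far more than the 200 changed here. These false calls therefore need not hold for the data. A cell cycle list lowered to 0.812 of its level was recovered in both lines with 0 false lists.

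The overlap expected from shared controls was read from 20 simulated experiments per line in which no group differed. Regroupings of the libraries used all 10 splits of 3 against 3 libraries, or 100 drawn regroupings with the real one among them. For 12755 genes with a 3' UTR of at least 50 bases, each of 15995 words of 7 bases found in at least 100 genes was regressed on the fold change, with UTR length and GC content in the model. Gene matching by identifier was added after the word results were first seen and changed them slightly. A planted word was ranked 1 in a trial of this method.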

Results

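Gene expression was measured by RNA sequencing in BE2C and Kelly, established human neuroblastoma cell lines that carry an amplified MYCN oncogene. Each line was infected with the lentiviral control vector pLKO-GFP or with 1 of 2 short hairpin RNAs against AHR, named shAhR-1 and shAhR-2. AHR encodes the aryl hydrocarbon receptor, a ligand-activated transcription factor. Each of the 6 groups held 3 libraries, 18 in all, with 32799682 to 45469353 counts per library over 39368 genes. The series title frames the question as whether the receptor holds MYCN-amplified neuroblastoma cells in a less differentiated state. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Expression is given as library-size scaled counts (CPM, mean ± SD, n = 3), and fold changes against the vector control of the same line are log2 values ± SE.

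AHR (chromosome 7, 16916359–17346152, plus strand, GRCh38, GENCODE release 29) had few counts in every library. The BE2C controls held 4, 4 and 6 AHR counts, the shAhR-1 libraries 8, 0 and 0, and the shAhR-2 libraries 0, 0 and 0. In Kelly the controls held 4, 26 and 29 counts, the libraries labelled shAhR-1 18, 11 and 22, and the shAhR-2 libraries 0, 4 and 0. Relative to the control, the pooled AHR rate in Kelly was 0.0660 with shAhR-2 (95% exact interval 0.0174 to 0.178) and 0.998 with shAhR-1 (0.672 to 1.48). In BE2C the ratio was 0 with shAhR-2, with an exact upper limit of 0.293, while the shAhR-1 ratio of 0.584 had an interval of 0.212 to 1.49. The 2-sided exact permutation test of AHR CPM gave p = 0.1 for BE2C shAhR-2, 0.4 for BE2C shAhR-1, 0.2 for Kelly shAhR-2 and 1 for Kelly shAhR-1, and 3 libraries against 3 cannot go below 0.1. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, AHR fell in Kelly with shAhR-2 (−3.84 ± 0.81, adjusted p = 3.41e-05) and was not called with shAhR-1 (−0.10 ± 0.54, adjusted p = 0.889). In BE2C it did not pass the expression filter, and with an interval reaching 1.49 no fall was shown for shAhR-1 in that line. Because AHR did not fall in the Kelly libraries labelled shAhR-1, a direction drawn from that group is a difference of those libraries from their control. Taken as the change from the mean Kelly control, each of these 3 libraries correlated over 14680 genes with BE2C shAhR-1 fold changes at r = 0.446 to 0.458 and with BE2C shAhR-2 fold changes at r = 0.00687 to 0.0212. These intervals treat each count as a separate fragment and cover counting error only. Low counts were mostly even, and with each library's AHR count halved and rounded up the upper limit for BE2C shAhR-2 was 0.675, and the Kelly shAhR-2 ratio was 0.0649 (0.00752 to 0.256).

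**Figure D1:**
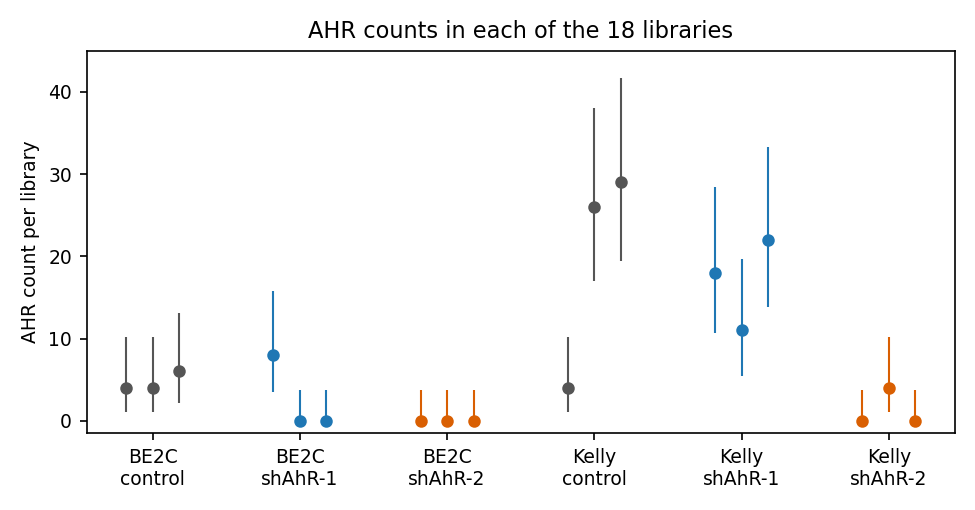
AHR counts in each of the 18 libraries (points, raw counts on the vertical axis) with 95% exact Poisson intervals (bars), by line and group. All 3 BE2C shAhR-2 libraries sit at 0, and the Kelly libraries labelled shAhR-1 hold 11 to 22 counts against 4 to 29 in their control.

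Genes of the receptor's own complex were measured alongside. ARNT, the dimerisation partner of the receptor, fell in all 4 contrasts, at log2 values of −0.39 ± 0.046 and −0.32 ± 0.045 in BE2C and −0.54 ± 0.038 and −0.23 ± 0.037 in Kelly (shAhR-1 first). The chaperone genes HSP90AA1 (−0.60 ± 0.027 and −0.96 ± 0.027 in BE2C, −0.45 ± 0.026 and −0.96 ± 0.026 in Kelly) and PTGES3 (−0.74 ± 0.028 and −1.13 ± 0.029, −0.61 ± 0.027 and −0.69 ± 0.027) fell as well. Of the 8 measured members of the AhR complex list, 4 fell and 1 rose with both shRNAs in each line, the same counts as adjusted over the list alone. In BE2C the riser was SRC. The list was not called in any contrast by camera (adjusted p = 0.0944 and 0.318 in BE2C, 0.136 and 0.189 in Kelly).

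The AhR target list held 9 measured genes in BE2C and 10 in Kelly and was not called in any contrast (camera adjusted p = 0.531 and 0.97 in BE2C, 0.59 and 0.735 in Kelly). In BE2C NFE2L2 rose with both shRNAs (0.37 ± 0.044 and 0.20 ± 0.044) and no member fell with both. In Kelly NQO1 (−1.40 ± 0.13 and −1.54 ± 0.13), a quinone reductase, and the amino acid transporter SLC7A5 (−0.28 ± 0.031 and −0.84 ± 0.032) fell with both. Adjusted over the list alone, the joint counts were again 1 in BE2C and 2 in Kelly. CYP1B1, a cytochrome P450 gene and textbook target of the receptor, rose in the Kelly libraries labelled shAhR-1 (1.55 ± 0.13, adjusted p = 1.31e-14) and fell with shAhR-2 (−1.72 ± 0.17). CYP1A1 stayed at or below 0.582 CPM in every group mean, and its BE2C shAhR-2 value of −1.02 ± 0.47 (adjusted p = 0.0489) lost its call with RLE scaling (adjusted p = 0.0519). TIPARP fell with shAhR-1 in BE2C (−0.32 ± 0.12, a call lost when single libraries were left out) and in Kelly (−0.38 ± 0.069) and was not called with shAhR-2 in either line (−0.01 ± 0.11, −0.03 ± 0.066). AHRR was not called in any of the 4 contrasts. In BE2C with shAhR-2 the target list's median was −0.01 while its mean was 0.27 and its test pointed up.

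The BE2C comparison asked which transcripts changed after either hairpin in that line, with the limit that no fall of AHR was shown with shAhR-1. MYCN (chromosome 2, 15940564–15947007, plus strand), the amplified driver of these tumours, fell from 2207 ± 31.8 CPM to 1842 ± 5.04 with shAhR-1 and 1136 ± 14.0 with shAhR-2 (−0.26 ± 0.024 and −0.96 ± 0.024, adjusted p = 4.49e-11 and 1.42e-26). Proliferation genes fell together. TOP2A (chromosome 17, 40388516–40417950, minus strand), the topoisomerase of dividing cells, dropped from 1195 ± 8.22 CPM to 454 ± 0.416 and 374 ± 8.15. The mitotic kinase gene PLK1 fell, at −1.40 ± 0.045 and −1.88 ± 0.046, and MAD2L1 of the spindle checkpoint went from 178 ± 2.98 CPM to 31.3 ± 0.476 and 67.4 ± 1.54. Of the 30 measured cell cycle genes, 28 fell and none rose with both shRNAs, and 28 also fell when adjusted over the list alone. The 2 others were MCM3 (−0.07 ± 0.034 and −0.84 ± 0.035, not called with shAhR-1) and MCM5 (0.10 ± 0.040 and −1.36 ± 0.043, risen with shAhR-1). Camera called the list down with both shRNAs (median −0.70 and −1.38, adjusted p = 1.21e-13 and 1.34e-12), and the call held with an estimated correlation (adjusted p = 0.00229 and 0.00287).

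MYC targets and cholesterol synthesis genes fell as groups in BE2C. Of 32 measured MYC targets 21 fell with both shRNAs (22 adjusted over the list alone) and PPAN rose, by 0.20 ± 0.070 and 0.21 ± 0.069. PPAN shares 59.8% of its exonic bases with another listed gene, so its counts are uncertain, and its call was lost when single libraries were left out. TFRC, the transferrin receptor gene, fell, at −0.94 ± 0.045 and −1.26 ± 0.045, the nucleolar protein gene NOP58 at −0.49 ± 0.032 and −0.67 ± 0.032 and the ribosome assembly gene RRS1 at −0.57 ± 0.056 and −0.95 ± 0.056. The list was called down with the preset correlation (adjusted p = 0.000227 and 4.11e-10). The calls were lost with an estimated one, at adjusted p = 0.271 and adjusted p = 0.061 with an estimated correlation. Cholesterol biosynthesis lost 15 of 22 members with both shRNAs (15 adjusted over the list alone), among them EBP (−0.87 ± 0.077 and −1.05 ± 0.077), DHCR7 (−0.67 ± 0.047 and −1.27 ± 0.048) and HMGCS1 (−0.63 ± 0.038 and −0.43 ± 0.037), enzymes of the pathway, and no member rose with both. Its test was down with both shRNAs (adjusted p = 0.000155 and 2.10e-05), with adjusted p = 0.0662 and adjusted p = 0.0465 with an estimated correlation.

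Genes of the sympathetic neuron program moved in both directions in BE2C. TH (chromosome 11, 2163929–2171877, minus strand), which encodes the rate-limiting enzyme of catecholamine synthesis, fell from 108 ± 3.22 CPM to 50.4 ± 4.38 and 72.6 ± 4.49. DBH (chromosome 9, 133635348–133659344, plus strand), the noradrenaline-forming enzyme, fell, at −0.42 ± 0.035 and −1.54 ± 0.036, while GCH1 (0.43 ± 0.078 and 1.82 ± 0.073) and the granin gene SCG2 (0.24 ± 0.028 and 1.10 ± 0.029) rose. Among 19 catecholamine genes 7 fell and 3 rose with both shRNAs, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.112 and 0.559). DCX (chromosome X, 111293779–111412429, minus strand), a microtubule gene of migrating young neurons, rose from 77.4 ± 2.33 CPM to 209 ± 5.06 and 499 ± 1.46, and KIF5C, a neuronal kinesin, rose by 0.77 ± 0.036 and 0.70 ± 0.036. The neurofilament gene NEFL (−0.73 ± 0.039 and −1.45 ± 0.041), MAP2 (−0.38 ± 0.028 and −0.58 ± 0.029) and CNTN1 (−0.40 ± 0.037 and −1.72 ± 0.039) fell. Of 29 neuronal differentiation genes 6 rose and 7 fell with both shRNAs (6 and 8 adjusted over the list alone), and the list was not called (adjusted p = 0.463 and 0.777). With shAhR-1 its median was −0.14, its mean 0.02 and its test pointed down.

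Among the adrenergic core regulators of BE2C, HAND2 (chromosome 4, 173524969–173530229, minus strand) fell, at −0.23 ± 0.028 and −2.18 ± 0.029, and ISL1 (0.48 ± 0.040 and 0.51 ± 0.040) rose. GATA3 was not called with shAhR-1 (0.06 ± 0.033) and had −0.09 ± 0.033 with shAhR-2, a call lost with a filter at 1 CPM (adjusted p = 0.418). In all 5 of 18 fell and 3 rose with both shRNAs, as they did adjusted over the list alone, with no call for the list (adjusted p = 0.782 and 0.515). With shAhR-1 the median was −0.10 and the mean 0.01, and the test pointed down.

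Among BE2C genes with a mean CPM of at least 5 and all 6 shRNA libraries beyond the 3 controls, the largest joint increases were those of MFAP4, CNN1, MMP15, LINC02593, ZNF853 and SERTM2. MFAP4 (chromosome 17, 19383442–19387240, minus strand), a microfibril-associated protein gene, rose from 2.08 ± 0.434 CPM to 14.4 ± 1.01 and 12.2 ± 1.00. CNN1, encoding a smooth muscle calponin, rose by 1.96 ± 0.22 and 5.46 ± 0.17, the metalloproteinase gene MMP15 by 1.75 ± 0.13 and 5.13 ± 0.10, LINC02593 by 1.85 ± 0.073 and 3.03 ± 0.070, ZNF853 by 1.77 ± 0.14 and 2.12 ± 0.13 and SERTM2 by 1.71 ± 0.063 and 2.54 ± 0.062. Under the same limits the largest joint decreases were those of TMSB15A (−1.81 ± 0.16 and −1.80 ± 0.16), CEND1 (−2.01 ± 0.13 and −1.77 ± 0.12), the cohesion factor gene CDCA5 (−1.54 ± 0.062 and −1.80 ± 0.062), CLSTN2 (−1.54 ± 0.068 and −2.25 ± 0.071), the anion channel gene LRRC8A (119 ± 5.72 CPM in the control, 42.1 ± 0.256 and 18.3 ± 2.11 with the shRNAs) and the histone variant gene H2AZ1 (−1.48 ± 0.033 and −1.53 ± 0.033).

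Several BE2C lists were called with 1 hairpin. With shAhR-2, 19 of 26 mesenchymal state genes rose and 3 fell (adjusted p = 0.0184, and adjusted p = 0.0753 with an estimated correlation), and with both shRNAs FN1 (0.37 ± 0.084 and 1.69 ± 0.079) and MAML2 (0.51 ± 0.12 and 1.37 ± 0.12) were among 5 that rose (6 adjusted over the list alone), while LGALS1 fell. TGF-beta response genes rose with shAhR-2 (16 of 21, adjusted p = 0.00235, and adjusted p = 0.061 with an estimated correlation), led among the named genes by LTBP2 (4.61 ± 0.097). With both shRNAs 7 of them rose, such as SMAD7 (0.45 ± 0.065 and 1.93 ± 0.061) and TGFBR2 (0.96 ± 0.10 and 1.74 ± 0.10), 8 adjusted over the list alone, and 3 fell, such as SKI (−0.68 ± 0.049 and −0.54 ± 0.048). Fibroblast markers and Schwann cell and glial markers rose in the same contrast by camera at the preset correlation (adjusted p = 0.0753 and 0.174 with an estimated one). Without the first shAhR-2 library, which stood apart from the other 2, adjusted p by camera at the preset correlation was 0.0168 for the mesenchymal list, 0.00225 for TGF-beta response, 0.000404 for fibroblast markers and 0.0777 for Schwann cell and glial markers, whose call was lost. A rise within the cells is not separated here from a change in the cells present. The 24 genes of the integrated stress and unfolded protein response were called down with shAhR-2 (21 fell, adjusted p = 8.05e-05, and adjusted p = 0.189 with an estimated correlation), whereas 12 rose and 4 fell with shAhR-1 (adjusted p = 0.14). With both shRNAs 4 fell, SHMT2 (−0.58 ± 0.040 and −1.37 ± 0.042) and MTHFD2 (−0.44 ± 0.036 and −1.03 ± 0.037) of mitochondrial folate metabolism among them, and VLDLR rose (2 risers adjusted over the list alone). Hypoxia response genes were called down with shAhR-1 (17 of 23, adjusted p = 0.000376, and adjusted p = 0.195 with an estimated correlation). With both shRNAs 10 fell, among them ALDOC (−1.01 ± 0.10 and −1.68 ± 0.10), and 2 rose, VEGFA (0.10 ± 0.032 and 0.41 ± 0.032, the shAhR-1 call lost when single libraries were left out) and MXI1, with no list call for shAhR-2 (adjusted p = 0.439). The same joint counts held adjusted over the list alone.

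Markers of other cell types were measured as fixed lists. Fibroblast markers rose with shAhR-2 in BE2C (11 of 13, adjusted p = 0.000479, and adjusted p = 0.0753 with an estimated correlation), with COL1A1 at 26.8 ± 2.63 CPM against 1.44 ± 0.296 in the control. With both shRNAs 5 rose, such as COL6A1 (0.66 ± 0.047 and 1.35 ± 0.046) and ACTA2 (1.65 ± 0.20 and 1.99 ± 0.20), and none fell. Schwann cell and glial markers rose with shAhR-2 (6 of 10, median 1.38, adjusted p = 0.0483, and adjusted p = 0.174 with an estimated correlation). That call held in 11 of 15 other settings at the preset correlation, and was lost with RLE scaling, at a mean CPM of at least 1, and without the third control or the first shAhR-2 library. The median did not move when members at 0 in the BE2C controls were set to their bound. PMP22 alone rose with both (0.21 ± 0.065 and 1.58 ± 0.061). Of 6 measured leukocyte markers none was called with both shRNAs (adjusted p = 0.767 and 0.777 for the list). Counts adjusted over each list alone were the same for these 3 lists.

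Replication-dependent histone genes rose with shAhR-1 in BE2C (8 of 16, adjusted p = 0.0391, and adjusted p = 0.195 with an estimated correlation), and 4 rose with both shRNAs, H2BC21 (1.82 ± 0.11 and 0.68 ± 0.12), H4C8 (2.28 ± 0.18 and 1.70 ± 0.19), H2BC5 (1.18 ± 0.11 and 1.05 ± 0.11) and H1-2 (1.05 ± 0.12 and 0.78 ± 0.12), while H1-5 fell. The list call held in 9 of 15 other settings at the preset correlation, and was lost without the second control, without the first or second shAhR-1 library and without any 1 of the shAhR-2 libraries (adjusted p = 0.0837 without the first). With shAhR-2 their median was 0.05, their mean −0.27, and the list was not called (adjusted p = 0.777). All 13 mitochondrially encoded mRNAs rose with shAhR-1 (adjusted p = 0.000376, and adjusted p = 0.584 with an estimated correlation), and 5 rose with both, MT-ND1 (0.54 ± 0.050 and 0.48 ± 0.050) and MT-CO1 (0.35 ± 0.048 and 0.26 ± 0.048) among them. The mitochondrial share of all counts was 19.1 ± 0.303% in the control, 24.5 ± 0.368% with shAhR-1 and 22.0 ± 2.64% with shAhR-2. Retinoic acid genes (15 measured, adjusted p = 0.14 and 0.194), p53 targets (20, adjusted p = 0.719 and 0.194) and interferon response genes (18, adjusted p = 0.602 and 0.255) were not called. With shAhR-2 more members still rose than fell. These were 10 and 3 retinoic acid genes (median 0.494), 12 and 4 p53 targets (0.758) and 11 and 5 interferon genes (1.08). With both shRNAs 3 retinoic acid genes rose and 3 fell, 4 p53 targets rose and 3 fell, TP53INP1 (1.22 ± 0.10 and 1.68 ± 0.098) and MDM2 (−1.13 ± 0.044 and −0.49 ± 0.042) in opposite directions, and 1 interferon gene rose and 3 fell (0 and 3 adjusted over the list alone, where the other counts were the same). With shAhR-1 the retinoic acid median was −0.21 and its mean 0.02, and the p53 test pointed down with median and mean of 0.02 and 0.02.

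In total 15732 genes were tested in BE2C by edgeR's quasi-likelihood test. With shAhR-1 3964 rose and 4270 fell, of which 632 and 434 changed at least 2-fold. With shAhR-2 5972 rose and 5845 fell, of which 2885 and 1491 changed at least 2-fold. At a mean CPM of at least 1 the balance turned, with 5244 risers and 5252 fallers. Both shRNAs together raised 2297 genes and lowered 2737, 5034 in all, and 1979 genes were called in opposite directions (28.2% of the genes called in both contrasts in any direction). The first shAhR-2 library stood apart, with a mitochondrial share of 25.1% against 20.5% in each of the others and a chi-square per degree of freedom of 20.9 and 22.8 against them, where other replicate pairs did not exceed 6.59. Without it 8366 genes were called with shAhR-1, 11554 with shAhR-2 and 5047 with both, and the same number of lists, 3, was called with both.

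**Figure D2:**
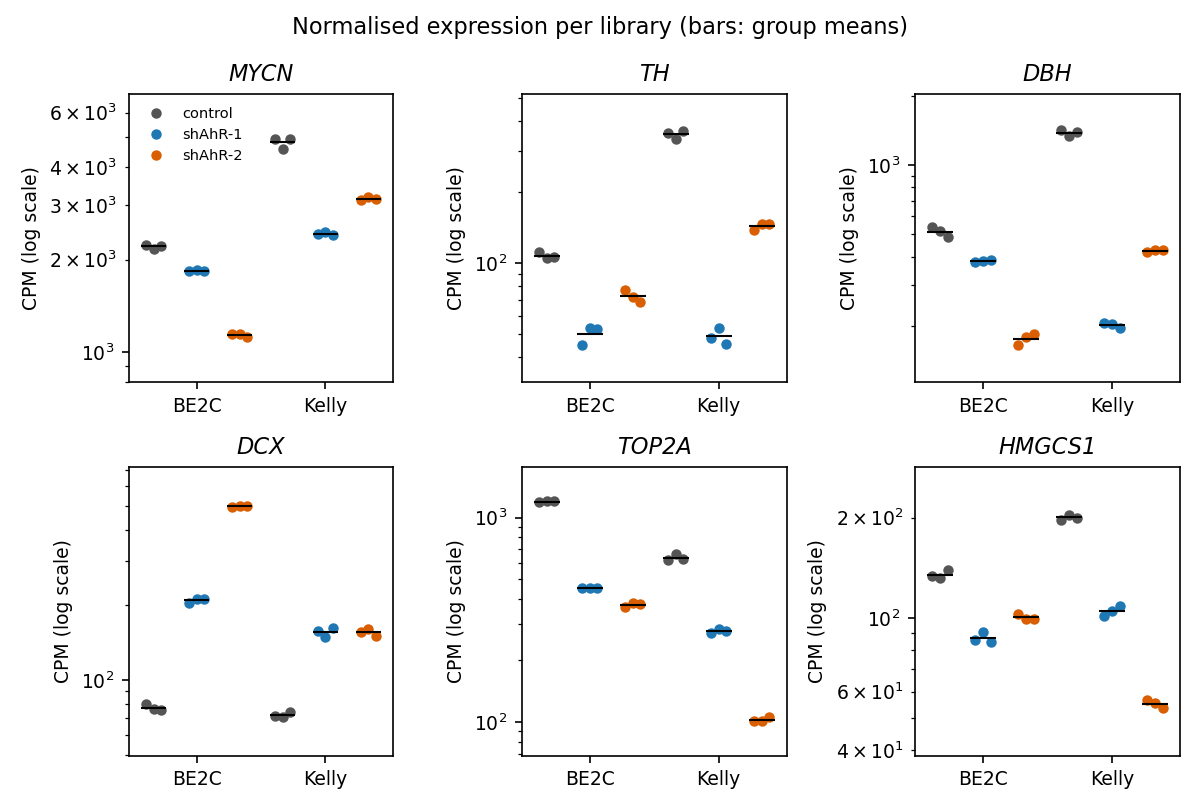
Normalised expression (CPM, log scale) of MYCN, TH, DBH, DCX, TOP2A and HMGCS1 in each library (points) with group means (bars), for BE2C on the left and Kelly on the right of each panel. MYCN falls from a mean of 2207 to 1842 and 1136 CPM in BE2C, and from 4816 to 2424 and 3147 CPM in Kelly.

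The Kelly comparison put the same question to the second line, with the limit that AHR did not fall in the libraries labelled shAhR-1. MYCN went from 4816 ± 218 CPM in the control to 2424 ± 31.8 and 3147 ± 35.3 (−0.99 ± 0.026 and −0.61 ± 0.026, adjusted p = 1.88e-35 and 2.52e-27). TH fell from 352 ± 14.1 CPM to 49.1 ± 3.76 and 144 ± 4.58, and DBH fell, at −2.76 ± 0.029 and −1.70 ± 0.028. SCG2 (chromosome 2, 223596940–223602503, minus strand) rose from 42.6 ± 1.59 CPM to 138 ± 2.87 and 486 ± 6.43, and CHGB, another granule protein gene, rose by 0.41 ± 0.029 and 0.58 ± 0.029. Of 19 catecholamine genes 7 fell and 4 rose with both shRNAs, in the same numbers adjusted over the list alone. The list was called down with shAhR-1 (13 fell, adjusted p = 0.0134, and adjusted p = 0.16 with an estimated correlation) and was not called with shAhR-2 (adjusted p = 0.883), where its median was 0.18, its mean −0.09 and its test pointed up.

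Among neuronal genes of Kelly, those called with both shRNAs rose more often than they fell. DCX rose from 72.4 ± 1.90 CPM to 156 ± 6.28 and 155 ± 4.67, and the stathmin gene STMN4 from 12.5 ± 0.983 to 52.1 ± 2.20 and 37.5 ± 2.30. NEFL (−0.64 ± 0.042 and −0.74 ± 0.042) and MAP2 (−0.43 ± 0.028 and −0.48 ± 0.028) fell. With both shRNAs 9 of 30 rose and 4 fell, also when adjusted over the list alone. Another 11 were called in opposite directions by the 2 hairpins, and with shAhR-1 12 rose and 12 fell. The list was called up with shAhR-2 (19 rose, 11 fell, adjusted p = 0.0473, and adjusted p = 0.127 with an estimated correlation) and not with shAhR-1 (adjusted p = 0.679). The shAhR-2 call held in only 6 of 15 other settings at the preset correlation (adjusted p up to 0.0662). Among adrenergic regulators HAND2 fell, at −0.23 ± 0.026 and −1.38 ± 0.027, and KLF7 at −0.43 ± 0.033 and −0.64 ± 0.033, and HAND1 (0.38 ± 0.028 and 1.26 ± 0.028) and SIX3 (0.53 ± 0.070 and 0.54 ± 0.069) rose. GATA3 was not called with shAhR-1 (0.03 ± 0.029) and fell with shAhR-2 (−0.26 ± 0.029). In the list 5 of 18 fell and 3 rose with both shRNAs, the same as adjusted over the list alone, and it was not called (adjusted p = 0.702 and 0.625).

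Cholesterol biosynthesis genes fell in Kelly. HMGCS1 (chromosome 5, 43289395–43313512, minus strand), an early enzyme of the mevalonate pathway, went from 200.4 ± 3.58 CPM to 105 ± 3.79 and 55.1 ± 1.47, and the squalene synthase gene FDFT1 fell, at −0.83 ± 0.051 and −1.70 ± 0.054. With both shRNAs 19 of 22 members fell and none rose, also when adjusted over the list alone. Camera called the list down (median −0.34 and −1.09, adjusted p = 0.000214 and 2.27e-08), with adjusted p = 0.115 and adjusted p = 0.0502 with an estimated correlation. The stress response list fell as well. SLC7A11, the cystine transporter gene, fell from 17.3 ± 0.872 CPM to 5.01 ± 0.481 and 0.348 ± 0.126, and the chaperone gene HSPA5 at −0.92 ± 0.026 and −0.97 ± 0.026, while VLDLR rose (0.59 ± 0.076 and 0.80 ± 0.074). With both shRNAs 11 of 24 fell (13 adjusted over the list alone) and 1 rose, with camera adjusted p = 0.0145 and 0.00425, and adjusted p = 0.173 and adjusted p = 0.127 with an estimated correlation.

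MYC targets fell in Kelly as well. LDHA, encoding lactate dehydrogenase A, fell, at −0.80 ± 0.029 and −1.51 ± 0.030 and NOP58 at −0.54 ± 0.033 and −0.51 ± 0.033, while PPAN rose (0.20 ± 0.084 and 1.21 ± 0.079, the shAhR-1 call lost with DESeq2). TFRC fell in the libraries labelled shAhR-1 (−0.81 ± 0.027) and rose with shAhR-2 (0.83 ± 0.027). With both shRNAs 15 of 32 fell and 1 rose, also adjusted over the list alone, and the list was called down with both (adjusted p = 0.00172 and 0.00425, and adjusted p = 0.115 and adjusted p = 0.127 with an estimated correlation). The cell cycle list behaved differently with each hairpin. With shAhR-2 all 30 members fell (median −2.41, adjusted p = 6.23e-15, and adjusted p = 0.0518 with an estimated correlation), and in the libraries labelled shAhR-1 12 fell and 7 rose (median 0.00, adjusted p = 0.54). The 12 that fell with both, 12 also adjusted over the list alone, included TOP2A (−1.19 ± 0.029 and −2.63 ± 0.032) and CDK1 (−0.60 ± 0.041 and −2.43 ± 0.046).

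Replication-dependent histone genes rose in Kelly. H4C8 rose by 1.23 ± 0.17 and 2.96 ± 0.15, H2BC5 by 1.16 ± 0.10 and 2.59 ± 0.093 and H2BC21 by 1.68 ± 0.10 and 1.27 ± 0.10. With both shRNAs 9 of 16 rose and 2 fell, H2AC20 (−2.22 ± 0.42 and −1.78 ± 0.39) and H4C3 (−1.08 ± 0.31 and −0.93 ± 0.30), also adjusted over the list alone. The list was called up (adjusted p = 0.046 and 0.0417, and adjusted p = 0.173 and adjusted p = 0.131 with an estimated correlation). That call was lost with RLE scaling, halved counts or mitochondrial genes left out, and without the first control or the third shAhR-2 library. With these genes, 11 of 13 mitochondrially encoded mRNAs rose in the libraries labelled shAhR-1 (adjusted p = 0.0134, and adjusted p = 0.598 with an estimated correlation) and 6 rose with both, such as MT-ND1 (0.52 ± 0.028 and 0.79 ± 0.028). The mitochondrial share of counts was 15.2 ± 0.616% in the Kelly control, 17.5 ± 0.139% with shAhR-1 and 15.5 ± 0.292% with shAhR-2. Mitochondrial mRNAs were not called as a list with shAhR-2 (adjusted p = 0.733).

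Hypoxia response genes fell in the Kelly libraries labelled shAhR-1 (17 of 22, adjusted p = 0.00135, and adjusted p = 0.115 with an estimated correlation) and were not called with shAhR-2 (adjusted p = 0.883). With both shRNAs 7 fell, such as PFKFB4 (−1.39 ± 0.095 and −0.77 ± 0.089), and MXI1 rose. Of 20 mesenchymal state genes 6 fell with both, NOTCH3 (−1.88 ± 0.080 and −1.22 ± 0.074) and ANXA2 (−1.66 ± 0.090 and −2.22 ± 0.094) among them, and 2 rose, and the list was not called (adjusted p = 0.931 and 0.338). TGF-beta response genes (19 measured, adjusted p = 0.168 and 0.644) included 5 that rose with both, such as SMAD7 (0.78 ± 0.098 and 1.54 ± 0.092), and 3 that fell, such as TGFB1 (−1.06 ± 0.056 and −1.26 ± 0.056). The p53 targets (20 measured, adjusted p = 0.0644 and 0.963) included 5 that rose, such as BTG2 (0.73 ± 0.048 and 0.92 ± 0.047), and MDM2, which fell (−0.94 ± 0.038 and −0.30 ± 0.036). Of 18 retinoic acid genes 3 fell with both, RARA (−0.67 ± 0.049 and −0.78 ± 0.049) among them (adjusted p = 0.136 and 0.861). Of 13 interferon genes 2 rose and 3 fell (adjusted p = 0.59 and 0.878). Joint counts adjusted over each of these lists alone were the same.

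Among lists of other cell types in Kelly, 1 of 12 fibroblast markers rose and 3 fell with both shRNAs (adjusted p = 0.219 and 0.861). None of 10 Schwann cell and glial markers (adjusted p = 0.0906 and 0.391) and none of 5 leukocyte markers (adjusted p = 0.763 and 0.644) was called with both in 1 direction by edgeR, also adjusted over the list alone. PMP22 fell in the libraries labelled shAhR-1 (−0.81 ± 0.063) and rose with shAhR-2 (1.23 ± 0.055). With shAhR-2, medians and means differed in sign for p53 targets (−0.03 and 0.04, test down), interferon genes (−0.50 and 0.19, test down) and fibroblast markers (0.09 and −0.19, test up). The retinoic acid median and mean were 0.03 and 0.01 while its test pointed down.

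Among Kelly genes within the same limits of CPM and separation, the largest joint increases were those of CREB5 (3.94 ± 0.10 and 3.09 ± 0.11), encoding a bZIP transcription factor, the phosphatase gene PTPRR (2.34 ± 0.15 and 2.37 ± 0.15), NT5E (2.30 ± 0.094 and 4.80 ± 0.079), which encodes the ecto-nucleotidase CD73, HELZ2 (2.06 ± 0.094 and 2.46 ± 0.091), the neuropeptide gene ADCYAP1 (2.05 ± 0.13 and 2.61 ± 0.12) and GPR137C (2.00 ± 0.090 and 2.67 ± 0.087). NT5E (chromosome 6, 85449584–85495791, plus strand) stood at 2.40 ± 0.246 CPM in the control and 67.1 ± 1.85 with shAhR-2. The largest joint decreases within these limits were those of DBH, MAD2L1 (−1.96 ± 0.043 and −2.19 ± 0.043), SLC7A11 (−1.79 ± 0.11 and −5.63 ± 0.17), RELL1 (−2.09 ± 0.14 and −1.75 ± 0.14), ANXA2 and the secreted glycoprotein gene STC1 (−2.65 ± 0.12 and −1.63 ± 0.11).

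In Kelly 15871 genes were tested. In the libraries labelled shAhR-1 4691 rose and 4915 fell, 734 and 797 of them at least 2-fold. With shAhR-2 5907 rose and 6063 fell, 2036 and 2008 of them at least 2-fold. That balance turned with RLE size factors (6079 and 5909) and in DESeq2 (6007 and 5752). With both shRNAs 2055 rose and 2262 fell, 4317 in all, and 3563 were called in opposite directions (45.2% of the genes called in both contrasts in any direction). By camera 4 of 20 lists were called with both shRNAs in Kelly and 3 of 20 in BE2C. With an estimated correlation 0 in Kelly and 1 in BE2C were called, and at an unadjusted p under 0.05 with that correlation the counts were 3 in Kelly and 2 in BE2C.

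**Figure D3:**
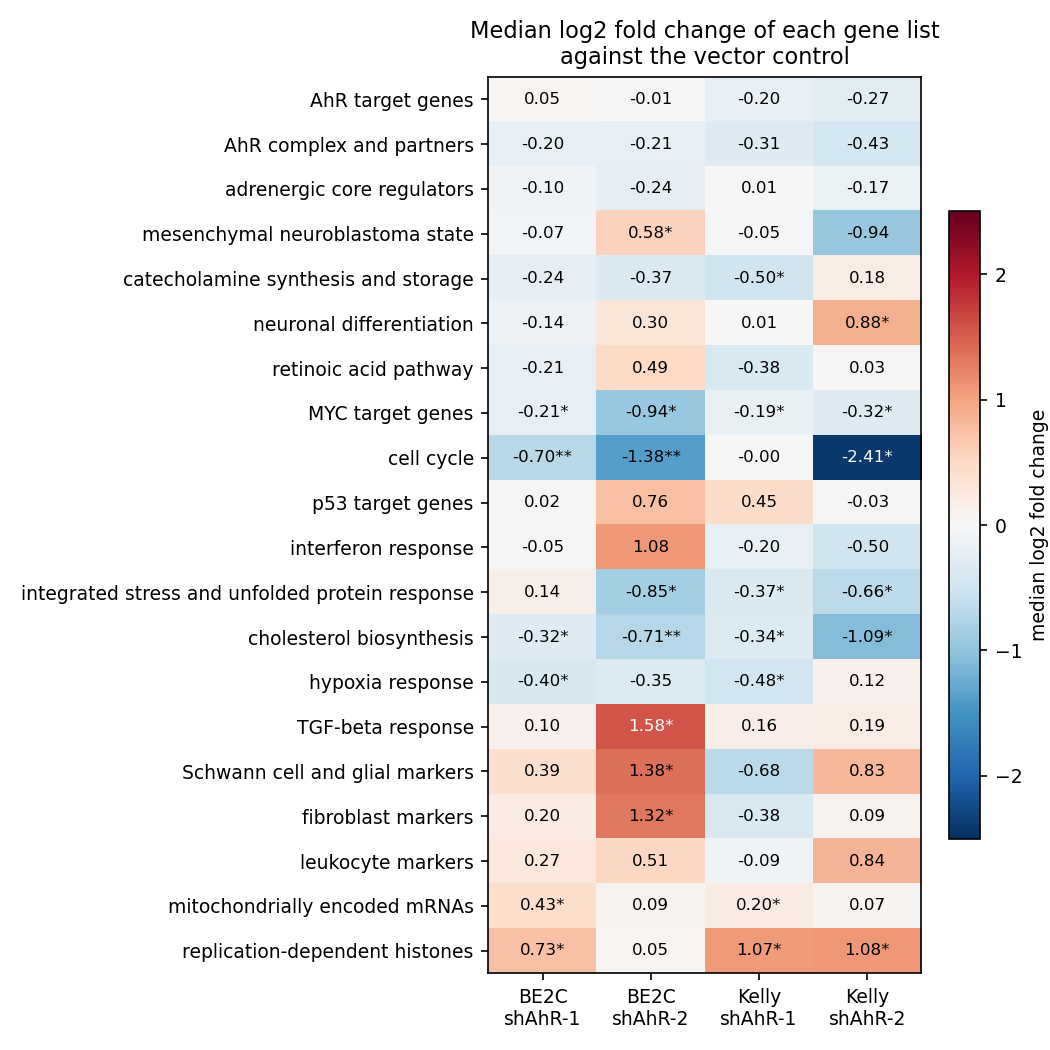
Median log2 fold change of each of the 20 gene lists (rows) in the 4 contrasts against the vector control (columns), on a blue to red scale from −2.41 for the Kelly cell cycle list with shAhR-2 to 1.58 for the BE2C TGF-beta list with shAhR-2. A single asterisk marks a camera call at the preset correlation and a second asterisk a call that also holds with the estimated correlation.

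Across both lines the question was which genes changed with both shRNAs everywhere. Of 14680 genes tested in both lines, 931 rose and 1303 fell in all 4 contrasts, 2234 in all and 83 of them at least 2-fold in each. Lists independent between the lines would share 297.4 risers and 407.6 fallers. Both lines received the same 2 hairpins, whose unintended effects can also be shared, so the excess does not measure an effect of AHR. By the lines, 87 genes were called in opposite directions. Without the first BE2C shAhR-2 library the count was 2236. Among shared risers within the same limits, those with the largest smallest change were the histone genes H2AC6 (2.39 ± 0.12 and 1.51 ± 0.12 in BE2C, 1.46 ± 0.083 and 2.76 ± 0.078 in Kelly) and H3C6 (2.13 ± 0.13 and 1.63 ± 0.13, 1.97 ± 0.14 and 1.13 ± 0.15), SERTM2 (2.68 ± 0.056 and 1.34 ± 0.059 in Kelly), the brain proteoglycan gene BCAN (1.16 ± 0.18 and 5.54 ± 0.13, 1.15 ± 0.15 and 4.27 ± 0.12), the p53 target TP53INP1 (1.14 ± 0.052 and 1.23 ± 0.051 in Kelly) and DCX. H2AC6 (chromosome 6, 26124145–26139116, plus strand) and H3C6 (chromosome 6, 26224199–26227473, plus strand) belong to the histone cluster on chromosome 6. Shared fallers picked in the same way were H2AZ1 (chromosome 4, 99948086–99950388, minus strand, −1.59 ± 0.033 and −1.89 ± 0.033 in Kelly), the DNA polymerase alpha gene POLA1 (−1.67 ± 0.049 and −1.46 ± 0.048, −1.51 ± 0.051 and −2.35 ± 0.054), RELL1 (−1.49 ± 0.091 and −1.46 ± 0.089 in BE2C), CLSTN2 (−1.44 ± 0.034 and −2.20 ± 0.035 in Kelly), MAD2L1 and the proteasome activator gene PSME3 (−1.41 ± 0.034 and −2.80 ± 0.036, −1.30 ± 0.033 and −2.19 ± 0.035).

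**Figure D4:**
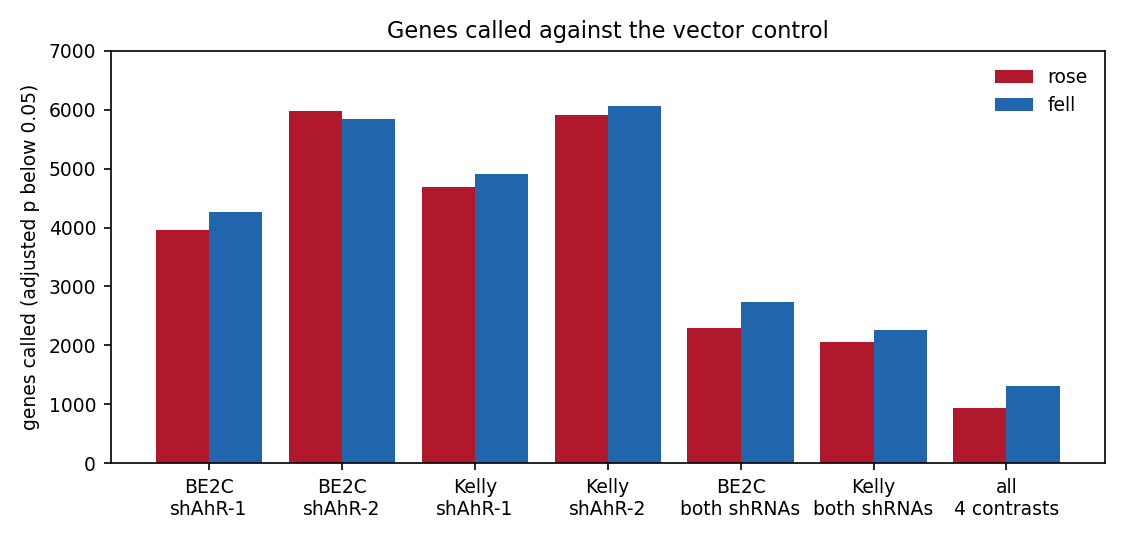
Genes called at an adjusted p below 0.05 (vertical axis, number of genes) that rose (red) or fell (blue) in each contrast against the vector control, with both shRNAs of a line in the same direction, and in all 4 contrasts. The counts run from 6063 fallers with shAhR-2 in Kelly to 931 risers shared by all 4 contrasts.

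The hairpins were also compared with each other, to see how far their effects differed. In BE2C 5653 genes were higher and 5743 lower with shAhR-1 than with shAhR-2 (11396 in all, 11104 without the first shAhR-2 library), and in Kelly 6231 were higher and 6058 lower (12289). CRABP2 (chromosome 1, 156699606–156705816, minus strand), encoding a cytosolic retinoic acid binding protein, stood at 3.17 ± 0.522 CPM with shAhR-1, 639.6 ± 24.8 with shAhR-2 and 6.17 ± 0.378 in the control of BE2C, a difference between the hairpins of −7.66 ± 0.058 (adjusted p = 1.28e-40). The kinesin gene KIF21B (−7.76 ± 0.23) and ELFN1 (−7.62 ± 0.21) were also lower with shAhR-1, and the lipid transporter gene ABCA12 (5.30 ± 0.090), the glutathione peroxidase gene GPX1 (3.62 ± 0.076) and C1QL1 (3.58 ± 0.10) were higher. In Kelly VWA5B1 (−7.97 ± 0.15), ELFN1 (−7.50 ± 0.17) and the anti-Müllerian hormone receptor gene AMHR2 (−6.88 ± 0.21) were lower with shAhR-1, and the guidance gene SEMA3C (6.56 ± 0.17), the GDNF-family receptor gene GFRA3 (5.33 ± 0.18) and the protocadherin gene PCDH19 (4.99 ± 0.078) were higher. GPX1 fell with shAhR-2 in both lines (−3.71 ± 0.075 in BE2C, −3.47 ± 0.057 in Kelly), and ELFN1 rose with shAhR-2 in both (7.55 ± 0.21, 6.25 ± 0.14).

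Between the hairpins the gene lists differed as well. In BE2C cell cycle genes were higher with shAhR-1 (28 of 30, adjusted p = 7.64e-08, and adjusted p = 0.012 with an estimated correlation). MYC targets (30 of 32, adjusted p = 1.89e-08, and adjusted p = 0.0917 with an estimated correlation), stress response genes (21 of 24, adjusted p = 4.40e-06, and adjusted p = 0.107 with an estimated correlation) and cholesterol genes (15 of 22, adjusted p = 0.0101, and adjusted p = 0.093 with an estimated correlation) were higher too. TGF-beta genes (17 of 21, adjusted p = 0.000643, and adjusted p = 0.0576 with an estimated correlation) and fibroblast markers (10 of 13, adjusted p = 0.000691, and adjusted p = 0.0917 with an estimated correlation) were lower with shAhR-1. So were mesenchymal state genes (16 of 26, adjusted p = 0.0104, and adjusted p = 0.0917 with an estimated correlation), retinoic acid genes (12 of 15, adjusted p = 0.0152, and adjusted p = 0.093 with an estimated correlation) and p53 targets (15 of 20, adjusted p = 0.0104, and adjusted p = 0.093 with an estimated correlation), while mitochondrial mRNAs were higher (11 of 13, adjusted p = 0.0122, and adjusted p = 0.633 with an estimated correlation). In Kelly all 30 cell cycle genes (adjusted p = 8.90e-14, and adjusted p = 0.0928 with an estimated correlation) and 19 of 22 cholesterol genes (adjusted p = 5.90e-05, and adjusted p = 0.0928 with an estimated correlation) were higher in the libraries labelled shAhR-1. Catecholamine genes (13 of 19, adjusted p = 0.0338, and adjusted p = 0.231 with an estimated correlation) and hypoxia genes (15 of 22, adjusted p = 0.0338, and adjusted p = 0.231 with an estimated correlation) were lower there. The hypoxia call was lost without the first library labelled shAhR-1 (adjusted p = 0.0545).

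Across genes, fold changes of the same hairpin in different lines correlated more than those of different hairpins in the same line. Pearson's r was 0.461 (Spearman's rho 0.521) for shAhR-1 and 0.623 (0.651) for shAhR-2 between lines, against 0.343 (0.356) between hairpins in BE2C and 0.0841 (0.0924) in Kelly. Genes are not independent replicates, so no p is given. Contrasts of 1 line share their 3 controls: simulated unchanged groups against them gave r = 0.507 (0.486 to 0.523 in 20 simulations) with a covariance of 0.0209 in BE2C, where the observed covariance was 0.286, and r = 0.496 (0.463 to 0.515) with 0.0163 in Kelly, where it was 0.0667. The differences in covariance were 0.265 and 0.0503. Of all genes 64.4% had the same sign with both hairpins in BE2C and 53.6% in Kelly, against 66.8% and 66.7% in the simulations, which held 0 joint calls. In groups without any change the shared controls alone set r and this share. Most genes were called here, so the simulated r and share cannot show whether the hairpins agreed less than shared controls would give. Independent lists of each hairpin's calls would share 1505 risers and 1586 fallers in BE2C and 1746 and 1878 in Kelly, with 3094 and 3621 genes in opposite directions. With 3 controls per line no split leaves 2 libraries on each side and none was run, so part of the excess of shared calls may come from the shared controls. Between lines, where no library is shared, 2367 genes rose and 2813 fell with shAhR-1 (1164 and 1351 if independent) and 815 were opposite (13.6%). With shAhR-2 3675 rose and 4116 fell in both lines (2076 and 2267 if independent) and 1531 were opposite (16.4%).

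**Figure D5:**
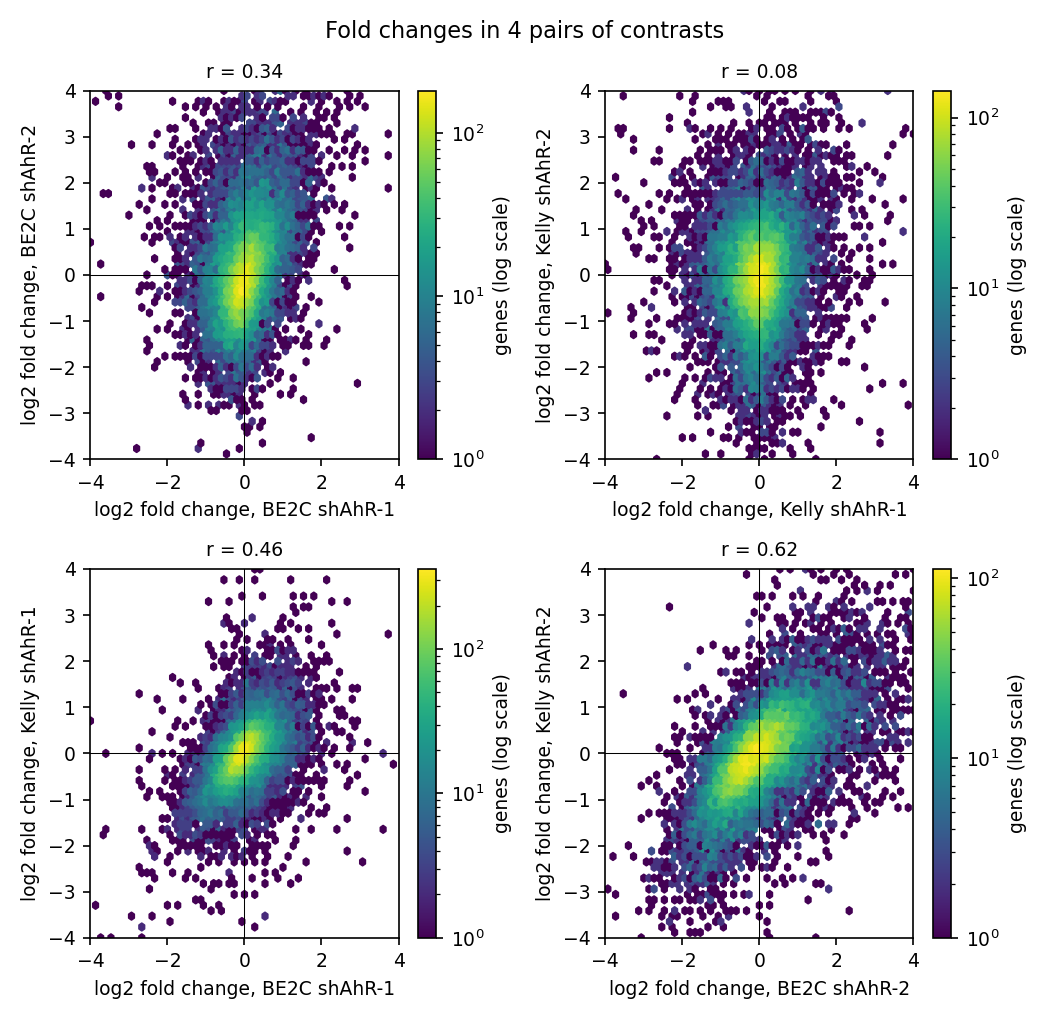
Log2 fold changes against the vector control of all genes tested in both contrasts of a panel, as hexagonal bins coloured by the number of genes (log scale), with axes drawn from −4 to 4. The panels compare both hairpins in BE2C (r = 0.34) and in Kelly (r = 0.08), and each hairpin between the lines (r = 0.46 for shAhR-1 and 0.62 for shAhR-2).

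The last comparison tested whether the mean effect of both shRNAs differed between the lines, with the Kelly libraries labelled shAhR-1 in that mean. The interaction, BE2C minus Kelly, was called for 7501 of 17136 genes (7471 without the first BE2C shAhR-2 library), 3795 above 0 and 3706 below, of which 954 and 275 exceeded 2-fold. The balance turned under other settings, with 3184 above and 4293 below without a low-count filter, 3262 and 4194 at a mean CPM of at least 1, 3637 and 3907 with RLE size factors and 3563 and 3849 in DESeq2, so it depends on the settings. In the mean of both shRNAs TH (1.23 ± 0.057, adjusted p = 4.78e-23) and DBH (1.24 ± 0.040, adjusted p = 4.76e-29) fell further in Kelly, and DCX (0.95 ± 0.043, adjusted p = 1.82e-23) rose further in BE2C. With shAhR-2 DBH fell by a similar amount in both lines, as given above. Its difference came mainly from shAhR-1, in whose Kelly libraries AHR did not fall. HMGCS1 (0.86 ± 0.044) also fell further in Kelly. HSPA5 (1.05 ± 0.034) fell with both shRNAs in Kelly, while in BE2C it rose with shAhR-1 (0.33 ± 0.029) and fell with shAhR-2. NT5E (−2.41 ± 0.086) and SCG2 (−1.94 ± 0.039) rose further in Kelly, and COL1A1 (4.03 ± 0.22), TGFB1 (2.12 ± 0.10) and CRABP2 (2.24 ± 0.089) were relatively higher in BE2C. No difference was called for ARNT (0.03 ± 0.051, adjusted p = 0.725), CLSTN2 (−0.08 ± 0.067, adjusted p = 0.372) or MXI1 (−0.04 ± 0.062, adjusted p = 0.633). The CLSTN2 interaction passed without a low-count filter, at −0.13 (adjusted p = 0.0256). A missed threshold does not show that the lines responded alike.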

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

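None of the tests here was chosen after its result was seen. The difference between the lines was called for 7501 of 17136 genes, 3795 with a mean shRNA effect higher in BE2C and 3706 with one higher in Kelly. The balance turned without a low-count filter (3184 and 4293), at a mean CPM of at least 1 (3262 and 4194), with RLE size factors (3637 and 3907) and in DESeq2 (3563 and 3849). In 100 regroupings of the libraries, the real one among them, 1 gave as many, and the highest other gave 4891. Of 137 named genes 103 were called, 58 above 0 and 45 below. Values are log2 differences, BE2C minus Kelly, from edgeR's quasi-likelihood test. The Kelly mean includes the libraries labelled shAhR-1, in which AHR did not fall.

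Among receptor genes the differences were CYP1B1 0.98, NFE2L2 0.19, NQO1 1.56, SRC 1.296, PTGES3 −0.29, HSP90AA1 −0.080 and SLC7A5 −0.33. Adrenergic regulators gave MYCN 0.19, HAND2 −0.40, ISL1 0.21, SIX3 −0.84, HAND1 −0.43 and KLF7 0.63. The MYCN value averages opposite differences, since MYCN fell less in BE2C than in Kelly with shAhR-1 and more with shAhR-2. In the catecholamine list TH had 1.23, DBH 1.24, GCH1 0.95, SCG2 −1.94 and CHGB −0.81. Neuronal genes gave DCX 0.95, NEFL −0.40, CNTN1 −0.94 and STMN4 −0.56, and the retinoic acid list RDH10 −1.01, STRA6 0.29, RARA 0.76 and CRABP2 2.24.

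Mesenchymal state genes differed by 1.36 for MAML2, 1.51 for FN1, −0.99 for ID1, 2.00 for NOTCH3 and 1.39 for ANXA2. TGF-beta genes gave TGFBR2 1.37, LTBP2 1.41, SKI −0.30, SMAD6 0.22 and TGFB1 2.12. Markers of other cells gave PMP22 0.67, ACTA2 1.53, COL6A1 1.06, COL1A1 4.03 and FBLN1 0.60. The MYC targets were PPAN −0.51, TFRC −1.11, RRS1 −0.53 and LDHA 0.19, and the cell cycle genes PLK1 −0.27, TOP2A 0.37 and CDK1 0.33. For p53 and interferon genes the values were TP53INP1 0.26, MDM2 −0.20, BAX −0.33, BTG2 −0.19 and OAS3 −0.31. Stress response genes gave SHMT2 −0.25, MTHFD2 −0.31, SLC7A11 2.15 and HSPA5 1.05. Cholesterol and hypoxia genes gave DHCR7 −0.23, HMGCS1 0.86, FDFT1 0.79, VEGFA 0.16 and PFKFB4 0.69. MT-ND1 had −0.15 and H2BC5 −0.76.

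Of the genes named for their joint changes in BE2C, MFAP4 had 2.52, CNN1 3.90, LINC02593 1.10, ZNF853 1.34, MMP15 2.34, CEND1 −0.69 and H2AZ1 0.23. Of those in Kelly, CREB5 had −2.18, PTPRR −1.48, NT5E −2.41, HELZ2 −1.68, ADCYAP1 −2.42, GPR137C −0.81, MAD2L1 0.12, RELL1 0.44 and STC1 0.72. Genes shared by all 4 contrasts still differed in size, with BCAN at 0.64, POLA1 at 0.36 and PSME3 at −0.36. Genes picked for a difference between hairpins gave ABCA12 −3.25, GPX1 −0.30, C1QL1 −0.94, KIF21B 2.00, ELFN1 1.24, GFRA3 1.09, PCDH19 1.18 and AMHR2 3.23. Among called genes with a mean CPM of at least 5 over the 18 libraries, differences named for their size were SALL1 6.24, MIR34AHG 5.45, CARTPT 4.33, ADAMTS20 4.28, ARSD −5.04, NACC2 −4.58 and SLITRK1 −3.82. SALL1, MIR34AHG and ADAMTS20 stood at 0 in the BE2C controls, ARSD and NACC2 at 0 in the Kelly controls and SLITRK1 at 0 with shAhR-1 in BE2C, so these fitted values depend on the prior count and are no bound.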

How the results depend on the processing

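Halved counts, also for AHR rates, and leaving out mitochondrial genes were tests chosen after the data were seen, and the others were fixed before the data were examined. With an estimated inter-gene correlation the lists called with both shRNAs went from 3 to 1 in BE2C, where the cell cycle list remained, and from 4 to 0 in Kelly, by camera. The p of called lists rose even where the estimate lay below the preset 0.01. For BE2C TGF-beta response with shAhR-2 the estimate was 0.000163, and camera p went from 0.000706 to 0.01. A call lost in this setting therefore does not show that correlated members had made it. Without single libraries (then under other settings), called genes ranged from 7488 to 8366 (7826 to 8242) for BE2C shAhR-1, 11383 to 11969 (10496 to 12078) for BE2C shAhR-2 and 10962 to 11626 (10164 to 11557) between hairpins. With both shRNAs in BE2C they ranged from 4664 to 5047 (4764 to 5062), with 3 lists whichever library was left out. In Kelly they ranged from 9026 to 9608 (9058 to 9612) for shAhR-1, 11553 to 12108 (10839 to 12093) for shAhR-2, 11963 to 12473 (11065 to 12523) between hairpins and 4036 to 4195 (3977 to 4322) with both, with 3 to 4 lists. All 4 contrasts gave 2125 to 2236 (2054 to 2246) and the interaction 7015 to 7471 (7376 to 7544). A replicate block gave 4953 genes with both shRNAs in BE2C, 4259 in Kelly, 2203 in all 4 contrasts and 7376 for the interaction, although residuals of equal replicate number did not pair (0 of 9 pairs over 0.1 in each line, −0.0966 to 0.0913 in BE2C and −0.0502 to 0.0567 in Kelly). DESeq2 gave 4764, 3977, 2054 and 7412. Of the named gene values under other settings, 8087 kept their status of called or not called, 148 lost a call and 31 gained one. In 0 a called change reversed its sign, and fold sizes were not compared.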

Other observations

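The tests of opposite directions, of seed matches as the whole of the agreement, of exchanged labels and of a partial knockdown were chosen after the fold changes and AHR counts had been seen. The other tests were set before their results were seen.

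Fold changes agreed more for the same hairpin between lines than for different hairpins within a line, and repression of unintended transcripts through seed matches in 3' UTRs may be part of this: the word most associated with lower fold changes in BE2C ranked 1 in Kelly for the same hairpin, GAGTCTA for shAhR-1 (effect −0.36 in BE2C, −0.33 in Kelly) and CCGACTA for shAhR-2 (−0.55, −0.51), and no better than 3406 of 15995 with the other. Of genes that fell at least 2-fold with the same hairpin, GAGTCTA occurred in 30.2% in BE2C and 16.9% in Kelly (6.41% of all genes), and CCGACTA in only 2.17% and 1.86% (0.925% of all genes). The t values of GAGTCTA were −17.73 in BE2C and −14.25 in Kelly. Those of CCGACTA were only −5.758 and −5.678, close to the next word of each line (−5.336 and −5.662). The AHR transcript holds GAGTCTA 2 times and CCGACTA 0 times, and 30.2% of all 7-base words. A seed match is thus less well shown for shAhR-2. As the whole of the agreement, direct 3' UTR matches of the shAhR-1 word are argued against. Over the 7262 of 12755 genes without its 6-base parts, r between lines was still 0.417 (0.479 over all). For shAhR-2 11536 genes lacked the parts, so r = 0.63 (0.633 over all) had little room to change and decides little. Matches of other words or outside the 3' UTR, and changes that follow from repressed genes, are not covered by this test. Of the BE2C genes called in both contrasts in any direction, 28.2% moved in opposite directions. This argues against a different strength of the same knockdown effect as the whole of the difference between hairpins. As a part of that difference it stays open, since effects of a single hairpin would also give opposite calls. GC content or transcript length is argued against by r = 0.626 after regressing both out (0.633 before, shAhR-2). How much of the rest is knockdown of AHR and how much is unintended stays open, since hairpin sequences are not given. Moreover, AHR did not fall in the Kelly libraries labelled shAhR-1, and no fall was shown with shAhR-1 in BE2C.

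AHR had few counts in every library. Reads shared with an overlapping gene could be discarded in counting, since 29.4% of the exonic bases of AHR lie in exons of AC019117.2 on the same strand, which the tables do not list. Genes with 20 to 50% of their bases covered in this way had a median control CPM of 2.03 and 45.5% of them lay under 1 CPM, against 7.56 and 38.2% with none covered, 12.0 and 25.3% with over 0 to 20% covered, 0.277 and 62.3% with over 50 to 80% covered, and 0 and 88.9% with over 80% covered. AHR may also be little transcribed in these lines, where the highest CPM of a control library was 0.754. On the annotation used here, discarding shared reads would remove only part of the AHR reads, since its other exonic bases stay countable. The annotation used for counting is not given, so the tables cannot tell how much each of the 2 contributes. Protein levels were not measured.

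AHR did not fall in the Kelly libraries labelled shAhR-1. An exchange of labels between Kelly groups is argued against, because each of these libraries correlated with BE2C shAhR-1 fold changes at r = 0.446 or more, where an exchange with the control predicts a negative r, and with BE2C shAhR-2 fold changes at 0.0212 or less, where an exchange with shAhR-2 predicts the higher r. An exchange made alike in both lines would not show in this test. A partial knockdown hidden by low counts may be present, since the exact interval of the AHR rate ratio with halved counts ran from 0.568 to 1.75. These counts cannot tell it from a failed knockdown.

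Regroupings of the libraries were compared with the real groups. For each contrast of 3 against 3 libraries only 10 splits exist, which are too few: the real split alone reached its count, 1 of 10, for BE2C shAhR-1 (8234), BE2C shAhR-2 (11817), BE2C shAhR-1 against shAhR-2 (11396), Kelly shAhR-1 (9606), Kelly shAhR-2 (11970) and Kelly shAhR-1 against shAhR-2 (12289), with 0 as the highest other in each. For genes called with both shRNAs, 4 of 100 regroupings reached the real count in BE2C (5034, highest other 7895) and 4 of 100 in Kelly (4317, highest other 7773), and for all 4 contrasts 4 of 100 did (2234, highest other 4383). In each line the 3 others kept the shAhR-2 libraries together as the reference (7877 to 7895 in BE2C, 7754 to 7773 in Kelly). The shAhR-2 libraries against all others thus gave more joint calls than both shRNAs against the control. The 91 with a mixed reference gave 0. Mixing groups puts their differences into the spread, here and in the splits of 3 against 3, so a count of 0 says little about chance. The joint counts of the lines and of all 4 contrasts share the same drawn regroupings. For the interaction 1 of 100 reached 7501, with 4891 as the highest other.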
